A study of Homo sapiens with 48 samples.

How the data were processed

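The series measured poly(A) RNA in 48 human 3D co-cultures by Illumina sequencing. Per the labels, each culture held mesenchymal stem cells, human umbilical vein endothelial cells and macrophages; the design text of the series calls the stromal cells fibroblasts. The macrophages were of the M1 phenotype (classical activation) or the M2 phenotype (alternative activation), and cultures of each phenotype were kept with or without polyethylene (PE) particles. Harvests on days 7, 14, 21 and 28 of 4 arms (M1, M2, M1+PE, M2+PE) make 16 groups of 3 libraries. Groups, days and replicate numbers were taken from the labels. A culture without macrophages was not analysed here.

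Per the labels, RNA was extracted with TRIzol, mRNA was captured on oligo(dT) beads and cDNA was primed with random hexamers. Per the submitters' processing notes, reads were handled with HISAT2 2.0.5 and featureCounts 1.5.0-p3. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. The deposited table of 57141 genes is called FPKM by name, but its values are raw read counts: whole numbers whose totals differ between libraries. All 57141 gene names are those of GENCODE release 29, which gave gene positions on GRCh38, exon lengths and exon overlaps. Of the columns, 0 could not be matched to a sample.

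The comparisons, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The planned test was limma on log2(FPKM + 1). Since the values are counts, the main test became edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), and the planned limma test (limma 3.58.1) was run on FPKM computed here from the counts and GENCODE exon lengths. Counts were scaled by TMM. One model of 16 group means was fitted to all 48 libraries, with 32 residual degrees of freedom, and each comparison was a two-sided contrast of group means weighting days or arms equally. The common dispersion was 0.180, a biological coefficient of variation of 42.5%, and the prior degrees of freedom were 5.63. Expression levels are given as CPM, counts scaled to a common library total. Genes with a CPM of at least 1 in at least 3 libraries were tested. A set of 514 Y-linked genes and X-inactivation transcripts were left out, leaving 18052 genes. P-values were adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05. Errors of log2 fold changes are standard errors (SE), the absolute log2 fold change divided by the square root of its quasi-likelihood F statistic, and errors of CPM are standard deviations over libraries.

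Nothing in the labels says that the 3 libraries of a group came from separate cultures or donors, so the p-values measure only the spread between these libraries, which may be technical. Total counts ran from 7840588 to 31197926 per library. For genes of mean CPM of at least 5, the 95% interval of a mean comparison reached a median of 0.32 log2, a 1.25-fold change, to either side; it covers the spread between libraries and the counting error. None of the 48 within-group pairs of libraries agreed within sampling noise (smallest chi-square per degree of freedom 8.15). The test was also run on simulated data of 17630 genes, drawn from the real means and library sizes. For each contrast 68, 66 and 66 genes, all of mean CPM of at least 5, were changed 1.5-, 2- and 4-fold. Libraries and genes were drawn independently, without structure shared between genes, so the shares do not give the recovery in the real libraries or for lower genes. In the simulation the particle contrast in M1 cultures recovered 36.8% of genes changed 1.5-fold, 92.4% of those changed 2-fold and 98.5% of those changed 4-fold. For the particle contrast in M2 cultures these shares were 51.5%, 87.9% and 97.0%, for the M2 to M1 contrast 45.6% at 1.5-fold and 92.4% at 2-fold, and for the time contrast 41.2% and 95.5%. The test of whether the M2 to M1 difference varied over days recovered 4.55% at 2-fold and 53.0% at 4-fold. Genes simulated without a change made up 13 calls (7.93% of all calls) for particles in M1 cultures, 17 (4.71%) for particles in M2 cultures, 13 (6.74%) for M2 against M1, 5 (2.69%) for time and 0 for the test over days.

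The 29 gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison; camera with an estimated correlation and fry were also run, as planned. After the results were seen, a test of each list's mean log2 CPM was added, with library labels permuted 100000 times within days (or within arms for the time comparison); the smallest p it can give is 1e-05. Beside each list stand the members past the threshold over all tested genes and the number past it when adjusted over the list alone.

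Genes named in the text follow a fixed rule. It takes, per mean comparison, the 8 largest rises and the 8 largest falls among genes past the threshold that moved the same way in each day (or arm) and had a mean of at least 5 CPM on the higher side. The rule was written for FPKM and was read as CPM. It adds 16 genes named in every comparison and the 3 members of each described list with the smallest adjusted p. CD68, among the 16 genes, shares 85.8% of its exon length with other genes and was not interpreted singly. It stayed a member of the pan-macrophage list, in its counts and in its means over all tested members. For the interaction most of the 16 genes are given as a range. Other genes whose counts are uncertain, because exons overlap those of another gene or because a near-identical copy exists, are marked where they appear. A fold change is not given where a group of 3 libraries held no counts. A gene that the rule names is not reported here.

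Settings varied as planned were another pseudocount (0.1), no low-value filter and a stricter one (mean CPM of at least 5), median-of-ratios and TPM scaling, quantile normalization, fits of only the groups compared, limma voom with array weights, a robust prior, a replicate block (the replicate number as a factor), an added 2-fold threshold, and leaving out each library in turn. The planned limma test as an alternative to edgeR, DESeq2 1.42.0, library totals without TMM, a block within each day, the same block in fits of the 2 arms compared, surrogate variables (sva 3.50.0, 6 variables, or 5 without a pair of libraries that stand apart), a fit without those 2 libraries and a fit without day 7 were chosen after seeing the data. Whether replicate numbers pair libraries was checked by correlating the deviations of same-numbered libraries from their group means, for each pair of arms on each day. All 3 correlations lay above 0.1 in 4 of 24 such checks, and there the numbers were taken to pair the libraries. These were M1 and M1+PE at day 7 (0.41 to 0.71), day 14 (0.39 to 0.77) and day 28 (0.23 to 0.63), and M2 and M2+PE at day 28 (0.19 to 0.57). The pairing comes from the correlations alone, since the labels do not say what a number shares. An exact one-sided test over the 4 days gave no pair of arms an adjusted p under 0.05 (smallest 0.102, M1 and M1+PE). For M2 and M2+PE the mean correlation over days was -0.086 (unadjusted p 0.721 by that test). The pairing is therefore an assumption.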

Results

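RNA was sequenced from 48 libraries of human 3D co-cultures that held macrophages, endothelial cells from umbilical vein and stromal cells. The stromal cells are called mesenchymal stem cells in the sample labels and fibroblasts in the design text. Macrophages of the M1 phenotype, the classically activated state, or of the M2 phenotype, the alternatively activated state, were cultured with or without polyethylene (PE) particles, a material worn off joint prostheses. Each of the 4 arms was harvested on days 7, 14, 21 and 28, with 3 libraries per arm and day. The stated purpose was to follow transcription, cytokine secretion and vessel formation in relation to macrophage phenotype; only transcript counts were analysed here.

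Total counts ran from 15578253 to 31197926 in 46 libraries, with 20822 to 29814 genes detected. The other 2 libraries, both from day 7, stood apart. Replicate 2 of the M2 arm had 7840588 counts and 38707 genes detected, and replicate 3 of the M2+PE arm had 9381188 counts and 36159 genes detected. In these 2 libraries mitochondrial transcripts took 1.144% and 1.129% of the counts (2.71% to 5.76% in the other 46) and pseudogenes took 3.93% and 2.16% (0.521% to 0.948%). FN1, which encodes the matrix protein fibronectin, took 0.286% and 0.497% of their counts, against 1.30% to 7.27% in the other 46. The first and second principal components of the 48 libraries held 22.6% and 18.7% of the variance. Since both libraries belong to M2 arms at day 7, counts of changed genes are also given without them.

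**Figure D1:**
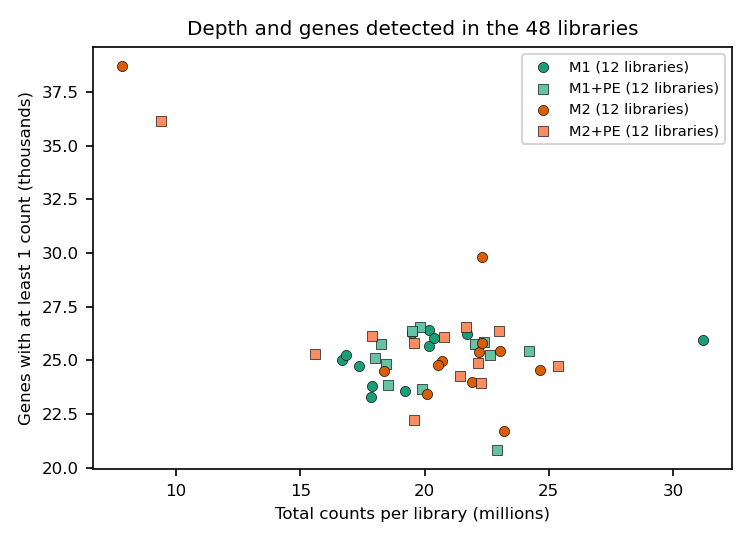
Number of genes detected against total counts per library, with 1 point for each of the 48 libraries. The 2 libraries at the top left, from the M2 and M2+PE arms at day 7, detected 38707 and 36159 genes, and the other 46 detected at most 29814.

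The first comparison asked how transcripts differed between cultures with M2 and with M1 macrophages in the absence of particles. Averaged over the 4 days, 20 of the 22 tested pan-macrophage markers rose in M2 cultures and none fell. Among single genes, CCL18, a chemokine of alternatively activated macrophages, rose by 3.61 ± 0.66 log2 (SE, 12 libraries per phenotype), from 0.864 ± 1.26 to 40.1 ± 89.4 CPM (SD). MARCO, a scavenger receptor of macrophages, rose by 3.27 ± 0.38 log2, from 65.1 ± 96.5 to 311 ± 233 CPM. ANGPT1, a ligand of the endothelial receptor TEK, fell by 1.39 on the log2 scale (SE 0.31), from 73.4 ± 26.7 to 28.5 ± 15.3 CPM. Each of these genes moved in the same direction on all 4 days. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 0.000492 for CCL18, 2.11e-06 for MARCO and 0.00274 for ANGPT1. MARCO (ENSG00000019169.10) lies on chromosome 2 at 118942166 to 118994660 and CCL18 (ENSG00000275385.1) on chromosome 17 at 36064280 to 36072032 (GRCh38, GENCODE).

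Other genes with large rises were MATK, a tyrosine kinase of blood cells (3.30 ± 0.61 log2), TNNT1, a troponin of slow muscle (3.13 ± 0.36), RGS1, a regulator of G-protein signalling in leukocytes (2.94 ± 0.93), and FCGBP, an Fc-binding protein of mucus (2.90 ± 0.44). KCNJ5, a potassium channel, and CD180, a surface receptor of B cells and macrophages, rose by 2.84 ± 0.49 and 2.83 ± 0.41 log2. The adjusted p of these 6 genes lay between 2.11e-06 (TNNT1) and 0.0364 (RGS1) by edgeR. Genes with large falls were ACKR4, a scavenging chemokine receptor (-1.63 ± 0.29 log2), ADH1B, an alcohol dehydrogenase (-1.57 ± 0.39), INSYN2B (-1.52 ± 0.28), and CEMIP, which takes part in hyaluronan breakdown (-1.52 ± 0.37). PDGFD, a platelet-derived growth factor, SVEP1, a matrix protein, and LVRN, an aminopeptidase, changed by -1.49 ± 0.36, -1.31 ± 0.23 and -1.29 ± 0.38 log2, with adjusted p of 0.00534, 0.000321 and 0.0265.

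The pan-macrophage markers that rose included C1QA and C1QB, subunits of complement C1q, at 2.30 ± 0.39 log2 each, and AIF1, a calcium-binding protein of macrophages, at 2.16 ± 0.36 log2. C1QA averaged 1186 ± 716 CPM in M2 cultures and 275 ± 310.4 in M1 cultures (SD, n = 12). All 22 passed when adjusted over the list alone. Of 22 tested genes of alternative activation, 12 rose and none fell (13 rose and 1 fell adjusted over the list alone). They included CD209, a C-type lectin (2.18 ± 0.39 log2), F13A1, a coagulation factor subunit (2.46 ± 0.47), CD163, the haemoglobin scavenger receptor (2.02 ± 0.46), and MRC1, the mannose receptor (1.98 ± 0.43). Of 25 phagocytosis, lysosome and foreign-body genes, 11 rose and none fell (14 rose and 1 fell adjusted over the list alone), among them the lipid scavenger receptor CD36 (1.93 ± 0.33 log2) and SPP1, which encodes osteopontin (2.55 ± 0.44). Of 13 class II antigen presentation genes, 9 rose and none fell (11 rose adjusted over the list alone), among them HLA-DPB1 (1.07 ± 0.22), HLA-DMB (1.55 ± 0.34) and HLA-DMA (1.08 ± 0.25). Of 17 osteoclast and bone-resorption genes, 5 rose and none fell (8 rose and 2 fell adjusted over the list alone), among them ACP5, the tartrate-resistant acid phosphatase (2.38 ± 0.36), TNFRSF11A, the receptor RANK (2.43 ± 0.40), and OSCAR, an immunoglobulin-like receptor of osteoclasts (1.45 ± 0.29).

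These 5 lists were the ones whose mean log2 CPM differed between phenotypes by permutation, with adjusted p of 0.000677 (pan-macrophage), 0.000677 (alternative activation), 0.00087 (phagocytosis), 0.00226 (class II) and 0.000677 (osteoclast). Without the 2 libraries that stood apart the same permutation test gave 0.000483, 0.000483, 0.000483, 0.00215 and 0.000653. By camera with a preset correlation 9 of the 29 lists passed, and 0 passed with an estimated correlation; fry called 6. For these 5 lists camera gave an adjusted p = 0.118, an adjusted p = 0.118, an adjusted p = 0.199, an adjusted p = 0.199 and an adjusted p = 0.199 with an estimated correlation, in the same order.

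Genes of classical activation went both ways. Of 24 tested, 5 rose and 1 fell (7 rose and 2 fell adjusted over the list alone). IRF5, a transcription factor, rose by 2.02 ± 0.38 log2, CD86, a costimulatory ligand, by 1.80 ± 0.48 and CD38, an NAD-consuming surface enzyme, by 1.24 ± 0.34. Of 24 interferon-stimulated genes 6 rose and 1 fell (7 rose and 1 fell adjusted over the list alone), with rises of BST2 (2.19 ± 0.29 log2), MX2 (1.496 ± 0.28) and OAS1 (1.51 ± 0.29), 3 genes of antiviral defence. Of 19 complement components 4 rose and 2 fell (6 rose and 3 fell adjusted over the list alone); besides C1q subunits, C2 rose by 1.57 ± 0.28 log2, although 38.7% of its exon length overlaps other genes. The median member of that list changed by -0.01 log2 and the mean member by 0.40. Of 24 endothelial markers 3 rose and none fell (3 rose adjusted over the list alone): FLI1, a transcription factor of endothelial and blood cells (0.98 ± 0.26 log2), EGFL7, a secreted endothelial protein (0.91 ± 0.28), and SOX17, a transcription factor (0.996 ± 0.33). Of 20 mesenchymal and fibroblast markers 1 rose and 2 fell (1 and 2 adjusted over the list alone). S100A4, a calcium-binding protein, rose by 0.91 ± 0.18 log2, and PDGFRA, a growth factor receptor, and DCN, the proteoglycan decorin, changed by -0.60 ± 0.14 and -0.73 ± 0.23. With an estimated correlation camera gave an adjusted p = 0.891 for classical activation, 0.838 for interferon, 0.98 for complement, 0.941 for endothelial and 0.98 for mesenchymal genes; the permutation test gave adjusted p of 0.263, 0.165, 0.172, 0.456 and 0.547. Mitochondrially encoded mRNAs, counted as a sign of RNA quality, were lower for all 13 genes, of which 1 fell (2 adjusted over the list alone; camera's adjusted p = 0.851 with an estimated correlation; permutation adjusted p 0.152, and 0.225 without the 2 libraries).

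Of the 15 interpretable genes fixed in advance, CD163 (adjusted p 0.00364) and MRC1 (0.00235) rose and 13 did not pass. The log2 differences of genes that did not pass were 1.45 ± 0.71 for CXCL10, 1.30 ± 0.67 for TNF and 1.55 ± 0.92 for IL1B, all inflammatory mediators, and 0.75 ± 0.94 for IL6, whose exons overlap another gene over 20.7% of their length. For the endothelial genes PECAM1, VWF and KDR they were 0.46 ± 0.26, 0.45 ± 0.32 and 0.19 ± 0.34. VEGFA, the main vascular growth factor, differed by 0.09 ± 0.22 log2 and the stromal genes COL1A1, PDPN and THY1 by 0.50 ± 0.21, 0.11 ± 0.20 and 0.17 ± 0.12. PRG4, which encodes lubricin, and MMP1, a collagenase, differed by -0.21 ± 0.31 and -0.26 ± 0.31 log2. The mean of MMP1 joins opposite days: it differed by -2.52 log2 at day 7, 1.285 at day 14, -0.16 at day 21 and 0.35 at day 28. MMP1 was not among the genes whose difference varied over days past the threshold.

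Over all 18052 genes, 1268 were higher and 610 lower in M2 cultures (1878 in all); 859 and 39 of them differed at least 2-fold. Without the 2 libraries that stood apart 1391 were higher and 719 lower. The balance of directions depended on scaling: TPM scaling gave 1081 higher and 998 lower, the planned limma test on FPKM 938 and 793, the same test with a pseudocount of 0.1 gave 1014 and 767, quantile normalization 938 and 1164, and limma voom with array weights 2554 and 2534. With surrogate variables 363 genes passed the threshold, and 9 pan-macrophage and 4 alternative activation genes rose. A fit without day 7 called 767 genes, and 20 pan-macrophage and 6 alternative activation genes rose (12 with all days). Leaving out a single library gave 1188 (without replicate 1 of M1 at day 28), 2941 (without replicate 3 of M2 at day 7) or 1178 genes (without replicate 1 of M2 at day 28).

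**Figure D2:**
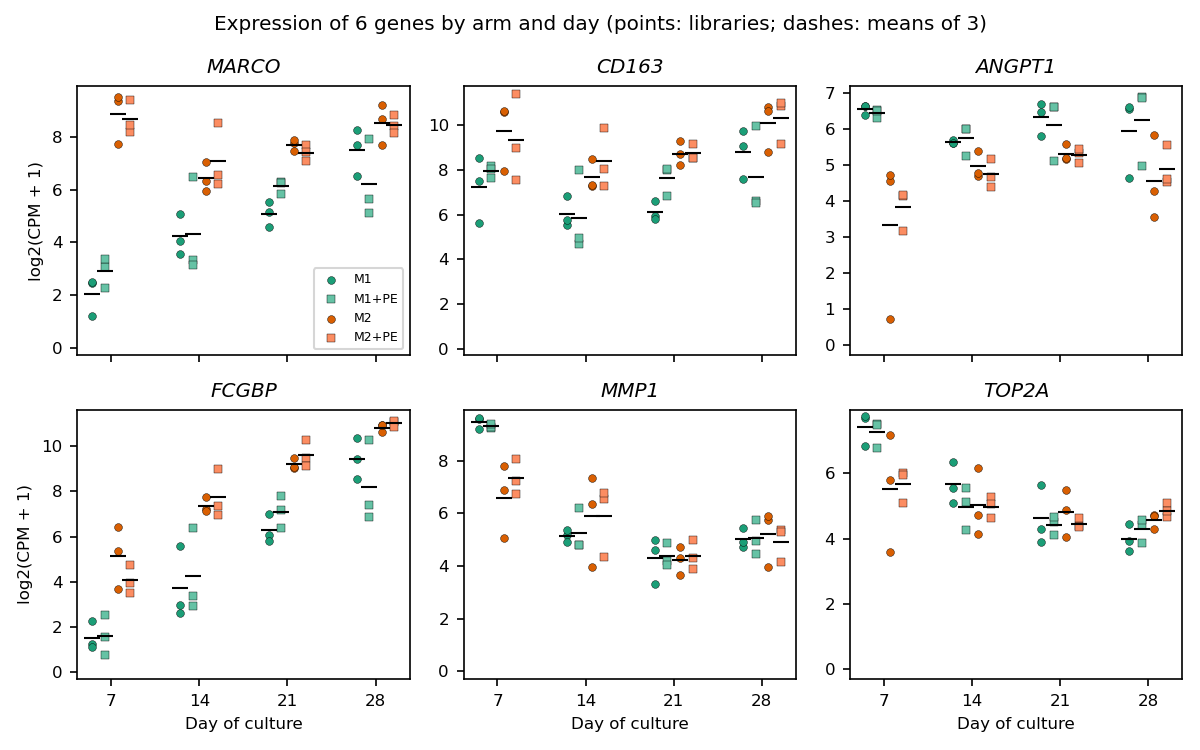
Expression of MARCO, CD163, ANGPT1, FCGBP, MMP1 and TOP2A as log2(CPM + 1) against harvest day for the 4 arms; points are single libraries and dashes are means of 3 libraries. By these means MARCO and CD163 lie higher and ANGPT1 lower in M2 and M2+PE cultures than in M1 and M1+PE cultures, and MMP1 and TOP2A lie lower at day 28 than at day 7. Single libraries overlap for each of these genes.

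The same phenotype comparison was made in cultures with particles, from separate libraries. Again 20 of the 22 pan-macrophage markers rose in M2+PE relative to M1+PE cultures and none fell (22 rose adjusted over the list alone), among them AIF1 at 1.94 ± 0.36 log2. IGSF21, a synaptic adhesion protein of the immunoglobulin family, rose by 3.31 ± 0.56 log2 (12 libraries per phenotype), MARCO by 2.85 ± 0.37 and FCGBP by 2.58 ± 0.44. ANGPT1 fell by 1.55 on the log2 scale (SE 0.31), from 75.8 ± 30.4 to 27.1 ± 11.7 CPM. By edgeR the adjusted p was 0.000268 for IGSF21, 7.15e-05 for MARCO, 0.000277 for FCGBP and 0.000981 for ANGPT1.

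Further large rises with particles were those of PKIB, an inhibitor of protein kinase A (2.60 ± 0.42 log2), CHST13, a chondroitin sulfotransferase (2.57 ± 0.39), and FOLR2, the folate receptor beta of macrophages (2.46 ± 0.43). FCGR2B, an inhibitory Fc receptor with near-identical copies, rose by 2.55 ± 0.44, and TMIGD3, which overlaps other genes over 21.2% of its exon length, by 2.52 ± 0.37. Large falls were those of INSYN2B (-1.85 ± 0.28 log2), ADH1B (-1.70 ± 0.40), ACKR4 (-1.62 ± 0.29), PDGFD (-1.55 ± 0.36) and CEMIP (-1.39 ± 0.37). EIF3CL, whose counts cannot be separated with certainty from its copy EIF3C, changed by -1.79 ± 0.55, and SLC2A12, a sugar transporter with 38.9% of its exons overlapped, by -1.57 ± 0.33.

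Among lists, 12 of 22 genes of alternative activation rose and none fell with particles (13 rose and 1 fell adjusted over the list alone), including CD209 (2.01 ± 0.38 log2), F13A1 (2.31 ± 0.47), and CLEC10A, a C-type lectin (2.54 ± 0.54). Of 25 phagocytosis, lysosome and foreign-body genes 12 rose and none fell (14 rose and 1 fell adjusted over the list alone). Among them were APOE, the lipid carrier apolipoprotein E (1.41 ± 0.21), and APOC1 (1.18 ± 0.20, with 43.2% of its exons overlapped). By harvest day, in order, APOE differed by 4.52, 0.80, 0.15 and 0.16 log2, and APOC1 by 4.10, 0.43, -0.29 and 0.47. These means thus rest mostly on day 7, whose M2+PE group holds a library that stood apart. Of 13 class II genes 7 rose and none fell (9 rose adjusted over the list alone), with HLA-DMA at 1.12 ± 0.25, HLA-DMB at 1.51 ± 0.34 and HLA-DPB1 at 0.92 ± 0.22 log2. Of 17 osteoclast genes 6 rose and none fell (7 rose and 2 fell adjusted over the list alone), with TCIRG1, a proton pump subunit, at 0.91 ± 0.14, ACP5 at 2.02 ± 0.35 and OSCAR at 1.48 ± 0.28. The permutation test gave adjusted p of 0.00131 for pan-macrophage, alternative activation and phagocytosis genes, 0.0157 for class II and 0.00087 for osteoclast genes, and 0.00087, 0.00167, 0.00087, 0.0105 and 0.00058 for these 5 lists without the 2 libraries that stood apart. By camera 8 of 29 lists passed with a preset correlation and 0 with an estimated one; the 5 lists had an adjusted p = 0.196, 0.196, 0.196, 0.408 and 0.304 with an estimated correlation. fry called 5 lists.

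Of 24 genes of classical activation 4 rose and 1 fell with particles (8 rose and 4 fell adjusted over the list alone). IRF5 rose by 2.01 ± 0.38 log2 and CD86 by 1.58 ± 0.47. Of 24 interferon-stimulated genes 6 rose and 1 fell (7 rose and 2 fell adjusted over the list alone), with BST2 at 1.86 ± 0.29, MX2 at 1.26 ± 0.28 and OAS1 at 1.30 ± 0.29. Of 19 complement components 5 rose and 4 fell (5 and 4 adjusted over the list alone), with C1QB at 2.20 ± 0.39, C1QA at 2.12 ± 0.39 and C2 (38.7% overlapped) at 1.52 ± 0.28. The median member of that list changed by -0.06 log2 and the mean member by 0.32. Of 24 endothelial markers 2 rose and none fell (2 rose adjusted over the list alone), namely EGFL7 (0.95 ± 0.28) and FLI1 (0.80 ± 0.26). CLDN5, a tight-junction protein, differed by 0.68 ± 0.29 and did not pass. Of 20 mesenchymal markers 1 rose and 4 fell (1 and 7 adjusted over the list alone), with S100A4 at 0.87 ± 0.18, PDGFRA at -0.63 ± 0.14 and FAP, a fibroblast surface protease, at -0.71 ± 0.23. Camera gave an adjusted p = 0.919 with an estimated correlation for each of these 5 lists, and the permutation test adjusted p of 0.266, 0.266, 0.137, 0.494 and 0.379. CD163 (1.82 ± 0.46 log2) and MRC1 (1.77 ± 0.43) rose and 13 of the 15 interpretable fixed genes did not pass. TNF differed by 1.86 ± 0.67 log2 with an adjusted p of 0.0501, VEGFA by 0.13 ± 0.22 and PECAM1 by 0.32 ± 0.25. CXCL10 differed by -0.17 ± 0.67, IL1B by 1.36 ± 0.91, VWF by 0.28 ± 0.32 and KDR by -0.11 ± 0.33. COL1A1, PDPN and THY1 differed by 0.32 ± 0.21, 0.23 ± 0.20 and 0.14 ± 0.12, and PRG4 and MMP1 by -0.38 ± 0.31 and -0.29 ± 0.31 log2. By day, MMP1 differed by -1.85 log2 at day 7, 0.80 at day 14, 0.044 at day 21 and -0.14 at day 28. IL6, with 20.7% of its exons overlapped, differed by 0.35 ± 0.94, and by -1.39 (adjusted p 0.0395) with surrogate variables and without the 2 libraries that stood apart. All 13 mitochondrially encoded mRNAs were again lower, of which 2 fell (2 adjusted over the list alone; camera's adjusted p = 0.919 with an estimated correlation; permutation adjusted p 0.116, and 0.169 without the 2 libraries that stood apart).

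In all, 1749 genes were higher and 1369 lower in M2+PE than in M1+PE cultures (3118), 784 and 92 of them at least 2-fold; without the 2 libraries that stood apart 2020 were higher and 1934 lower. TPM scaling, which moved the median of all genes by -0.13 log2, gave 1221 higher and 2943 lower, library totals without TMM 1618 and 1916, the planned limma test 1361 and 1696, and quantile normalization 1278 and 1617. With surrogate variables 419 genes passed, and 3 pan-macrophage and 1 alternative activation genes rose. A fit without day 7 called 823 genes, and 18 pan-macrophage and 9 alternative activation genes rose (12 with all days). Of the genes higher in M2, 990 were shared with the comparison without particles (123 by chance from the list sizes), and of those lower 526 (46.3 by chance); 1 gene was called in opposite directions. Over both particle conditions 3137 genes were higher and 2842 lower in M2.

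When the days were taken singly, with 3 libraries against 3, genes past the threshold were found at day 7. Without particles 1991 genes were higher and 929 lower in M2 at day 7, and with particles 1900 were higher and 1924 lower. Only 7 genes had an M2 to M1 difference without particles that varied over the 4 days, by edgeR's quasi-likelihood F test, and 1590 had an unadjusted p under 0.05. For APOE the difference was 4.05 log2 at day 7, 1.05 at day 14, -0.37 at day 21 and -0.37 at day 28 (adjusted p 0.000207), and for MARCO it was 7.27, 2.19, 2.63 and 0.996 (adjusted p 0.0224). APOC1, an apolipoprotein whose exons are 43.2% overlapped, CFD, the complement factor D, and RSPO2, a Wnt agonist, were also higher in M2 at day 7 (3.36, 3.75 and 2.96 log2), and PF4V1, whose counts are uncertain beside its copy PF4, and PID1 were lower (-2.37 and -2.76). At days 14, 21 and 28 edgeR called 0 genes. At an unadjusted p under 0.05 the counts on these days were 932, 1131 and 657 without particles and 1491, 528 and 1520 with particles. DESeq2 called 5, 127 and 6 genes without particles and 12, 5 and 10 with particles, voom 6, 815 and 4091 and 6085, 301 and 5084, and the planned limma test 0, 0 and 0 and 0, 0 and 3.

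The day 7 counts rested on few libraries and on the spread shared by all 48. A fit of only the 6 libraries compared called 0 genes at day 7 without particles and 170 with particles, and 511 and 116 at day 21. With surrogate variables 411 and 549 genes passed at day 7. Without the 2 libraries that stood apart 259 genes passed in the comparison without particles and 2418 in that with particles. For the comparison without particles the count was 392, 527, 183 or 6627 on leaving out replicate 1 of M1, replicate 2 of M1, replicate 2 of M2 or replicate 3 of M2. With particles it was 1822, 2188 or 904 on leaving out replicate 1 or replicate 2 of M1+PE or replicate 3 of M2+PE. With particles, leaving out replicate 1 of M1+PE at day 14 gave 670 genes on that day, and leaving out replicate 3 of M1+PE at day 28 gave 633. The count of varying genes fell to 1, 2, 1 and 1 without replicates 1, 2 or 3 of M1 or replicate 2 of M2 at day 7, and was 335 without replicate 3 of M2 at day 7.

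The particle comparison asked whether polyethylene changed transcripts within a phenotype. No gene passed the threshold of edgeR's quasi-likelihood test in M1 cultures or in M2 cultures, averaged over the 4 days. At an unadjusted p under 0.05 there were 81 genes (0.449% of those tested) in M1 and 236 (1.31%) in M2 cultures, fewer than a uniform distribution of p-values would give. DESeq2 called 5 genes in M1 and 0 in M2 cultures, and the planned limma test and voom called 0 in both. A fit of the M1 and M1+PE libraries with the replicate number as a block within days called 1 gene, RGS1 (named after its value was seen), at 1.54 log2 (adjusted p 0.00478; 1.53 and adjusted p 1 without the block). Over all 4 days, same-numbered M1 and M1+PE libraries had a mean correlation of 0.38 (exact one-sided p 0.017, adjusted p 0.102). Pairing over all days was thus neither established nor excluded. The numbers were taken to pair these libraries on 3 of the 4 days. At day 21, when they were not, the fit with the block gave RGS1 5.16 log2. Averaged over both phenotypes, edgeR again called 0 genes (167 at an unadjusted p under 0.05), and 0 without the 2 libraries that stood apart (270).

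Among phagocytosis and foreign-body genes no difference between cultures with and without particles passed the threshold. In M1 cultures MARCO differed by 0.48 ± 0.35 log2, CD36 by 0.64 ± 0.32 and TREM2, a lipid-sensing receptor of macrophages, by 0.68 ± 0.39; in M2 cultures APOE differed by 0.36 ± 0.20, PLIN2, a lipid-droplet protein, by 0.24 ± 0.14 and TREM2 by 0.69 ± 0.37. Among inflammatory mediators, CXCL10 in M1 cultures had a difference of 2.07 log2 (95% interval 0.62 to 3.52; unadjusted p 0.00623, adjusted p 1), from 0.616 ± 0.999 to 2.12 ± 3.67 CPM, in the same direction on all 4 days. TNF, IL1B and IL6 differed by -0.33 ± 0.69, 0.28 ± 0.91 and 0.23 ± 0.94 log2 in M1 cultures and by 0.24 ± 0.64, 0.08 ± 0.89 and -0.17 ± 0.94 in M2 cultures. CSF2, a growth factor of myeloid cells with groups at 0 counts, averaged 0.144 ± 0.226 CPM with and 0.316 ± 0.418 without particles in M1 cultures. CCL7 and CCL5, both chemokines, differed by 0.42 ± 0.45 and 0.27 ± 0.30 in M1 cultures, and CCL8, IL24 and IL11 by 0.36 ± 0.41, 0.34 ± 0.42 and -0.50 ± 0.78 in M2 cultures. Among osteoclast genes ATP6V0D2, a proton pump subunit, differed by 1.09 ± 0.43 log2 in M1 (adjusted p 1) and 0.48 ± 0.40 in M2 cultures, ACP5 differed by 0.75 ± 0.35 in M1 (unadjusted p 0.0362, adjusted p 1) and 0.39 ± 0.34 in M2 cultures, and OSCAR by 0.35 ± 0.28 and 0.38 ± 0.28. Among secreted angiogenic factors FGF1, TGFA and MDK differed by 0.25 ± 0.16, 0.54 ± 0.41 and -0.14 ± 0.15 in M1 cultures, and VEGFB, PTN and TGFA by 0.24 ± 0.13, -0.33 ± 0.24 and 0.37 ± 0.37 in M2 cultures. VEGFA differed by 0.04 ± 0.22 in M1 and 0.07 ± 0.22 log2 in M2 cultures, PECAM1 by 0.46 ± 0.26 and 0.32 ± 0.25, and MMP1 by 0.03 ± 0.31 and 0.01 ± 0.31. The differences in M1 and M2 cultures were 0.50 ± 0.45 and 0.29 ± 0.45 for CD163, 0.54 ± 0.42 and 0.34 ± 0.42 for MRC1, 0.58 ± 0.33 and 0.42 ± 0.32 for VWF and 0.49 ± 0.34 and 0.20 ± 0.33 for KDR. For COL1A1 they were 0.24 ± 0.21 and 0.063 ± 0.21, for PDPN 0.032 ± 0.20 and 0.16 ± 0.20, for THY1 0.041 ± 0.12 and 0.0069 ± 0.12, and for PRG4 0.077 ± 0.31 and -0.088 ± 0.31.

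Of the 29 lists, no member passed in either phenotype, over all genes or adjusted over the list alone. Camera with a preset correlation called 13 lists in M1 and 6 in M2 cultures, and 0 in both with an estimated correlation; fry called 0. The camera list of smallest p in M1 cultures was that of endothelial markers, with all 24 members above 0 and a median of 0.38 log2 (adjusted p 5.69e-16 with the preset and adjusted p = 0.236 with an estimated correlation; permutation adjusted p 0.957). For genes of mean CPM of at least 5, the 95% interval of the particle difference lay within 2-fold for 96.2% of genes in M1 and 96.9% in M2 cultures, which leaves smaller changes open. For several named genes the interval reached beyond 2-fold, so larger changes stay open there. In M1 cultures it was -1.56 to 2.12 log2 for IL1B, -1.675 to 2.13 for IL6 and -1.72 to 1.06 for TNF. It reached 1.405 log2 for CD163, 1.39 for MRC1 and 1.45 for ACP5. In M2 cultures it was -1.72 to 1.89 log2 for IL1B, -2.07 to 1.73 for IL6 and -1.05 to 1.53 for TNF. The particle by phenotype interaction also called 0 genes by edgeR (132 at an unadjusted p under 0.05; DESeq2 1, planned limma and voom 0), with intervals within 2-fold for 92.2% of genes. The difference between the particle effects in M2 and M1 cultures was -1.62 ± 0.96 log2 for CXCL10, 0.57 ± 0.94 for TNF, 0.32 ± 0.20 for PLIN2, 0.23 ± 0.20 for TCIRG1 and 0.31 ± 0.19 for VEGFB, none past the threshold. It was 0.31 ± 0.29 for APOE, -0.41 ± 0.45 for CD36, -0.56 ± 0.62 for CCL7, 0.54 ± 0.81 for CSF3, -0.61 ± 0.58 for ATP6V0D2, -0.39 ± 0.51 for TNFSF11, -0.34 ± 0.33 for PTN and -0.22 ± 0.22 for FGF1. For the other 13 interpretable fixed genes it lay between -0.40 ± 1.33 (IL6) and 0.12 ± 0.29 (PDPN). Per day edgeR called 0 genes in all 8 particle comparisons. The counts at an unadjusted p under 0.05 at days 7, 14, 21 and 28 were 47, 33, 165 and 228 in M1 and 1717, 233, 305 and 44 in M2 cultures. On the days when replicate numbers were taken to pair the libraries, a fit of the 2 arms with the number as a block also called 0 genes. With it 161, 182 and 2073 of 16311 genes in M1 cultures at days 7, 14 and 28, and 7 of 17302 in M2 cultures at day 28, had an unadjusted p under 0.05. The count in M1 cultures at day 28 is more than a uniform distribution of p-values would give, and the other 3 are fewer. DESeq2 called 5, 1, 4 and 5 and 63, 1, 0 and 1; the planned limma test called 1 gene in M2 cultures at day 7 and voom 1 at day 28. In M2 cultures at day 7 the edgeR count was 28 without replicate 3 of M2, 13 without replicate 1 of M2+PE and 6 without replicate 2 of M2+PE.

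Time in culture had the largest count of changed genes among the 6 mean comparisons. Between day 7 and day 28, averaged over the 4 arms, all 24 tested cell cycle genes fell, 11 of 19 complement components rose, and 12 of 24 matrix-degrading enzymes and inhibitors fell. FCGBP rose by 7.12 ± 0.54 log2 (12 libraries per day), and CD28, a costimulatory receptor first described on T cells, by 5.01 ± 0.43, from 0.716 ± 0.494 to 24.9 ± 16.9 CPM. MMP1, a collagenase, fell by 3.17 on the log2 scale (SE 0.34), from 410.4 ± 284 to 35.1 ± 14.6 CPM. In single libraries of day 7, MMP1 lay between 595 and 786 CPM in M1 arms and between 32.8 and 268.5 in M2 arms. At day 28 it lay between 21.0 and 53.1 CPM in M1 arms and between 14.6 and 57.9 in M2 arms. The arms thus parted at day 7 and overlapped at day 28. The adjusted p was 1.37e-12 for FCGBP, 1.5e-11 for CD28 and 2.73e-09 for MMP1 by edgeR, and each gene moved the same way in all 4 arms. FCGBP (ENSG00000275395.5) lies on chromosome 19 at 39863323 to 39934626 and MMP1 (ENSG00000196611.4) on chromosome 11 at 102789920 to 102798160 (GRCh38).

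Other large rises over time were those of ASPN, the matrix proteoglycan asporin (4.37 ± 0.67 log2), GATM, an enzyme of creatine synthesis (4.24 ± 0.36), WISP2, a CCN-family matricellular protein (3.88 ± 0.37), CD200R1, an inhibitory receptor of myeloid cells (3.81 ± 0.57), and FOS, an immediate-early transcription factor (3.81 ± 0.79). C7, a complement component without counts in a group, averaged 10.9 ± 7.12 CPM at day 28 and 0.919 ± 2.19 at day 7 (adjusted p 7.3e-08). Large falls were those of NOS1, the neuronal nitric oxide synthase (-7.06 ± 0.97 log2), and AOC1, a diamine oxidase (-6.22 ± 0.81). The other 6 of the largest falls had groups without counts, so that no fold is given. At day 7 RASAL1 averaged 5.98 ± 9.30 CPM, CCL22, a chemokine of alternatively activated macrophages, 16.9 ± 17.5, NCCRP1 5.05 ± 6.26, MUCL1 7.57 ± 15.9, LAMP3, a marker of mature dendritic cells, 10.3 ± 11.7 and NPHS1 6.39 ± 15.9. At day 28 their means lay between 0.00349 ± 0.0121 (NPHS1) and 0.139 ± 0.147 CPM (LAMP3), with adjusted p from 6.68e-11 (CCL22) to 0.00794 (NPHS1). The day 7 means of these 6 genes include the 2 libraries that stood apart, and each SD exceeds its mean. For NPHS1 the estimated fall was larger in the M2 and M2+PE arms, which hold those libraries, than in the M1 and M1+PE arms. Values without those libraries are not given here.

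The median cell cycle gene changed by -2.22 log2, and all 24 also fell when adjusted over the list alone. CDC20, an activator of the anaphase-promoting complex, changed by -3.28 ± 0.33, and the mitotic cyclins CCNB1 and CCNB2 by -2.63 ± 0.27 and -2.57 ± 0.24. Of 19 complement components 11 rose and 1 fell (11 and 1 adjusted over the list alone); SERPING1, the C1 inhibitor, rose by 1.67 ± 0.17 log2 and C4B, whose counts are uncertain beside its copy C4A, by 3.14 ± 0.43. Of 24 interferon-stimulated genes 13 rose and 1 fell (14 and 1 adjusted over the list alone), with IFIT1, IFIT2 and IFIT3 at 2.26 ± 0.27, 2.71 ± 0.33 and 1.41 ± 0.24. Of 20 hypoxia and glycolysis genes 7 rose and 3 fell (9 and 3 adjusted over the list alone). EGLN3, an oxygen sensor, rose by 3.00 ± 0.37, PDK1, a brake on pyruvate oxidation, by 1.33 ± 0.18 and KDM3A, a histone demethylase, by 0.87 ± 0.17. Of 13 class II genes none rose and 8 fell (9 adjusted over the list alone), among them HLA-DPB1 (-1.83 ± 0.22), HLA-DOA (-1.42 ± 0.31) and CIITA, the class II transactivator (-1.35 ± 0.18, with 23.4% of its exons overlapped). Of 24 matrix-degrading enzymes and inhibitors 3 rose and 12 fell (4 and 12 adjusted over the list alone), with MMP3, the stromelysin, at -4.53 ± 0.53 and MMP8, a neutrophil collagenase, at -3.54 ± 0.44. Of 16 synovial lining genes 4 rose and 5 fell (4 and 5 adjusted over the list alone); besides MMP1 and MMP3, CRTAC1, a cartilage matrix protein, changed by -5.98 ± 0.50, whereas PRG4, the lubricin gene of lining cells, rose by 2.02 ± 0.32.

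Of 11 markers of other blood cells none rose and 7 fell (9 adjusted over the list alone). GNLY and NKG7, proteins of cytotoxic granules, changed by -4.51 ± 0.41 and -3.18 ± 0.57 log2, and CD8A averaged 1.82 ± 3.04 CPM at day 7 and 0.0724 ± 0.115 at day 28. Of 24 inflammatory cytokines and chemokines 1 rose and 14 fell (1 and 14 adjusted over the list alone), including CXCL5 (-3.41 ± 0.40), IL24 (-3.88 ± 0.46) and CXCL6 (-2.02 ± 0.27). Of 24 endothelial markers 3 rose and 5 fell (2 and 4 adjusted over the list alone). SOX17 and PLVAP, a protein of fenestrated endothelium, changed by -1.43 ± 0.33 and -1.39 ± 0.33, and FLI1 rose by 0.99 ± 0.26. Of the 15 interpretable fixed genes PRG4 rose, TNF (-2.21 ± 0.66), IL6 (-2.69 ± 0.995, 20.7% overlapped), COL1A1 (-0.56 ± 0.21), THY1 (-0.34 ± 0.12) and MMP1 fell, and 9 did not pass, among them CD163 (0.66 ± 0.45), VEGFA (0.52 ± 0.22, adjusted p 0.0508) and CXCL10 (1.64 ± 0.69, adjusted p 0.0524). The other 6 were MRC1 (0.86 ± 0.42), IL1B (-1.61 ± 0.91), PECAM1 (0.53 ± 0.26), VWF (-0.27 ± 0.32), KDR (-0.56 ± 0.34) and PDPN (-0.059 ± 0.20).

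By permutation of list means 9 of the 29 lists changed over time, with adjusted p of 0.00029 for cell cycle, complement and blood cell lists, 0.0133 for interferon and class II, 0.0102 for hypoxia, 0.011 for matrix-degrading and pericyte genes and 0.0303 for synovial lining genes; endothelial markers (0.478) and inflammatory cytokines (0.125) did not pass. Without the 2 libraries that stood apart the values were 0.00029 for the first 3 lists, then 0.0206, 0.00515, 0.0149, 0.000507, 0.00515 and 0.000812, and 0.0156 for inflammatory cytokines, whose mean log2 CPM differed by -1.86 then and by -1.37 over all libraries. Camera called 8 lists with a preset correlation and 0 with an estimated one, where the adjusted p = 0.165 for cell cycle, 0.516 for complement and blood cells, 0.872 for interferon, class II, hypoxia, matrix-degrading and inflammatory genes and 0.952 for synovial lining and endothelial genes.

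**Figure D3:**
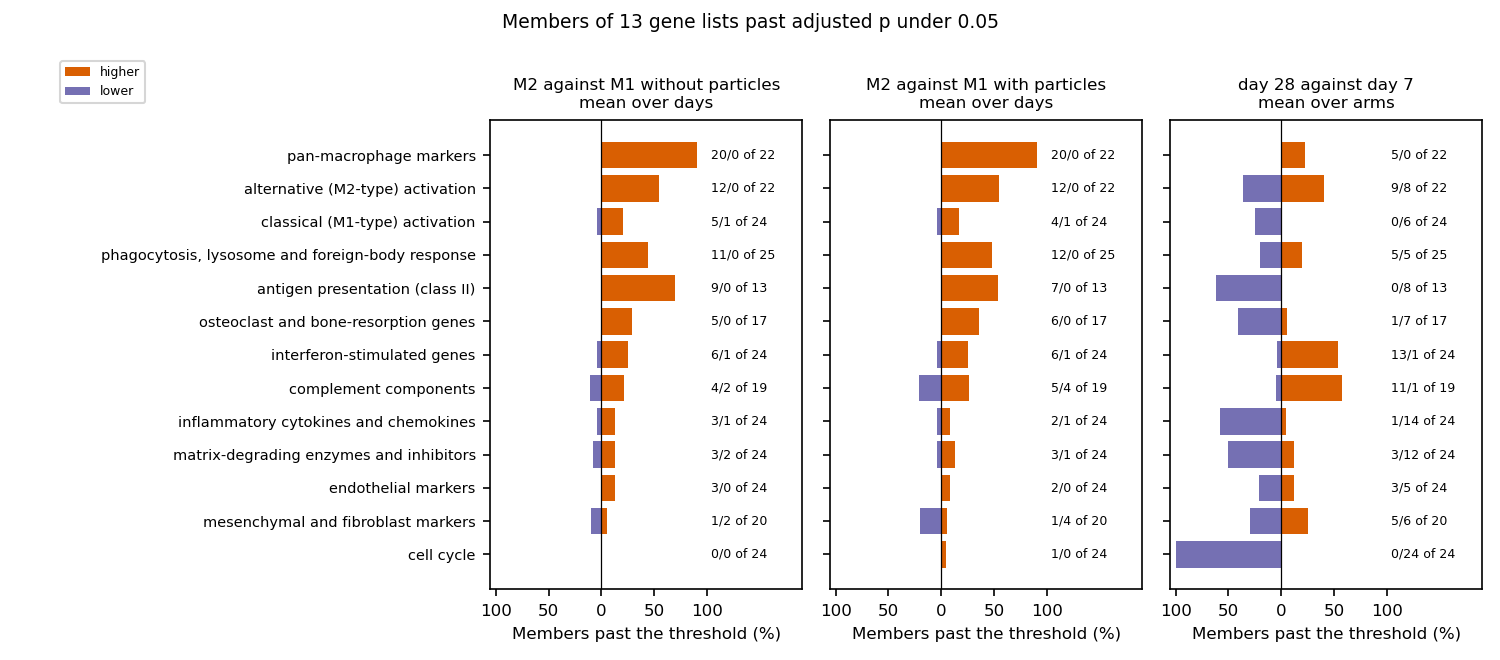
Percent of the tested members of 13 gene lists that were higher or lower past the threshold in M2 against M1 cultures without particles, in M2 against M1 cultures with particles, and at day 28 against day 7. Pan-macrophage markers were higher in 20 of 22 members in both phenotype comparisons, and cell cycle genes were lower in 24 of 24 members at day 28.

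Over all genes 3747 were higher and 3930 lower at day 28 than at day 7 (7677), 1121 and 1801 of them at least 2-fold, and without the 2 libraries that stood apart 4533 were higher and 3925 lower. TPM scaling, which moved the median of all genes by 0.16 log2, gave 5252 higher and 2947 lower, and the planned limma test 4512 and 2793, or 4729 and 2730 with a pseudocount of 0.1 (median 0.14). With surrogate variables 4640 genes passed the threshold, and TNF (1.16 log2) and SOX17 (0.15 log2) no longer passed and lay above 0; without the 2 libraries as well, KDM3A (-0.014 log2) also no longer passed and lay below 0. Mitochondrially encoded mRNAs, a sign of RNA quality, rose for 3 of 13 genes at day 28 and fell for none (3 and none adjusted over the list alone; permutation adjusted p 0.226, and 0.477 without the 2 libraries that stood apart).

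Within single arms, with 3 libraries against 3, 774 genes rose and 947 fell in M1, 441 and 1165 in M2, 476 and 780 in M1+PE and 2148 and 2173 in M2+PE cultures. Without the 2 libraries that stood apart the totals were 3441, 557, 2558 and 3749. The change over time differed between M2 and M1 cultures for 11 genes (8 without the 2 libraries) and between M2+PE and M1+PE cultures for 2 genes (3 without). Of the 11 genes, the log2 change in M2 minus that in M1 cultures was above 0 for 2 and below 0 for 9. The totals moved with single libraries. Replicate 2 of M2 at day 7 moved them also in arms it does not belong to, to 2697 in M1 and 1931 in M1+PE cultures. In M1 they were 882 and 913 without replicates 1 and 2 at day 7 and 872 without replicate 2 at day 28. In M2 they were 3103, 405 and 3341 without replicates 1, 2 and 3 at day 7 and 500, 339 and 183 without those at day 28. In M1+PE they were 592 and 531 without replicates 1 and 2 at day 7 and 560 and 686 without replicates 1 and 2 at day 28. In M2+PE they were 2209 without replicate 3 at day 7 and 2697 without replicate 1 at day 28.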

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

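The tests of library size and of the M2 phenotype for the pair of libraries that stand apart, all tests of the macrophage share, and the correlations and parted pairs of same-numbered libraries, were chosen only after the result was seen.

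Some genes drew attention because an effect differed between days or phenotypes. The M2 to M1 difference without particles varied over the 4 days for 7 genes, and the change from day 7 to day 28 differed between M2 and M1 cultures for 11 genes and between M2+PE and M1+PE cultures for 2 genes. Of 60 splits of the libraries within days, 3, the real one included, gave at least 7 varying genes and the highest of the others gave 327, so chance cannot be excluded for the varying genes. What gave that split several times the real count was not tested. Leaving out single libraries moved the real count between 1 and 335.

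A signal outside the comparisons appeared in genes with at most 2 counts in the other 46 libraries. Of 16340 such genes, 6448 had counts in replicate 2 of M2 at day 7 and 5435 in replicate 3 of M2+PE at day 7, which is 1.54% and 0.496% of the counts of these libraries.

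These 2 libraries detected more genes than any other library, and library size, phenotype and an even spread of reads were weighed. Against library size, the other 46 libraries thinned to 7840588 counts detected at most 25127 genes, below the 36159 of the lower of the pair. Against the M2 phenotype at day 7, 3 of the other 4 M2 and M2+PE libraries of that day detected no more genes than the highest M1 or M1+PE library. In the otherwise silent genes, counts per exon kilobase were 1.54 times as high in lncRNA as in protein-coding genes (1.47 in the second library) and rose with exon length (Spearman's rho across genes 0.36 and 0.33), as stated in advance for reads spread evenly over exons. Residual DNA is a candidate explanation for the extra genes detected. If such reads lay evenly over all exons they would make up 19.1% and 6.17% of the counts. Shares of that size would not lower mitochondrial transcripts or FN1 from the other 46 libraries' range (at least 2.71% and 1.30%) to the values found here. Evenly spread reads alone therefore do not account for those low shares, and a different origin of such reads stays open.

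Macrophage genes were higher in M2 cultures, which may come from a larger share of macrophage RNA or from a different state of the macrophages. Structure among the libraries that the labels do not give is a further candidate. With surrogate variables 9 pan-macrophage genes rose without and 3 with particles, against 20 in each main fit, so that candidate stays open. Without the 2 libraries that stand apart, 20 of the 20 pan-macrophage genes that rose without particles still rose, which argues against them as the cause. A larger share alone would leave the gap between pan-macrophage and M1-type genes equal in both phenotypes; for 13 of the 24 genes of classical activation, picked by hand as made by macrophages, it differed by 0.87 log2 (SE 0.26, permutation p 0.00594, adjusted 0.0119) without and 0.73 log2 (SE 0.29, p 0.0121, adjusted 0.0182) with particles, which argues against a larger share alone, but for the 8 of mean CPM of at least 5, a restriction added after these values were seen, by 0.61 log2 (SE 0.37, p 0.166, adjusted 0.332) and 0.33 log2 (SE 0.39, p 0.402, adjusted 0.603), so share and state cannot be told apart with these 8 genes. Over the whole list it differed by 1.32 log2 (SE 0.28, p 0.00056, adjusted 0.00168) and 1.24 log2 (SE 0.32, p 0.00013, adjusted 0.00078), and over its members of mean CPM of at least 5 by 1.23 log2 (SE 0.37, p 0.00877, adjusted 0.0132) and 1.03 log2 (SE 0.39, p 0.00739, adjusted 0.0132), but the rest of that list was left out as also made by other cells, which a larger share need not raise. For genes of mean CPM of at least 5 the gap between M2-type and pan-macrophage genes differed by -0.48 log2 (permutation p 0.00239, adjusted 0.00717) and -0.57 log2 (p 0.00125, adjusted 0.00717), also unlike a larger share alone unless other cells make M2-type genes, while that between M2-type and M1-type genes differed by 0.13 log2 (SE 0.42, p 0.787) and -0.24 log2 (SE 0.42, p 0.573), 0.13 (p 0.712) and 0.014 (p 0.964) with all 13, and 0.58 (p 0.12) and 0.52 (p 0.0944) with the whole list, so no shift from M1-type to M2-type genes passed and the polarization that the design names stays open.

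The particle comparison of M1 cultures gave fewer small p-values than a uniform distribution would, with 0.449% of genes at an unadjusted p under 0.05. Structure among the libraries that the labels do not give could raise the spread within groups. With surrogate variables the share was 2.40%, and with a replicate block within each day in a fit of the M1 and M1+PE libraries it was 2.18% (at day 28 alone 2073 of 16311 genes), both between the bounds stated in advance, so neither can be told apart from other causes. Same-numbered M1 and M1+PE libraries of a day had a mean correlation of 0.38 (exact one-sided p 0.017, adjusted over 6 pairs of arms 0.102), which leaves batches that share a number open. Against the 2 libraries that stand apart as the cause, the share without them was 0.724%.

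In 60 splits of the libraries within days, no other split gave as many genes as the real one for M2 against M1. The counts were 1878 genes without particles and 3118 with particles, each reached by 1 split, the real one, and the highest other count was 1 in both. For day 28 against day 7, with 60 splits within arms, 7677 genes were reached by 1 split and the highest other was 1854. For these 3 counts the share of splits lay under 0.05, so a random split of single libraries is unlikely to give them. Chance is not excluded if the 3 libraries of a group share a culture or donor, which the labels leave open. For particles in M1 cultures, in M2 cultures and the interaction, the real count was 0, which all 60 splits reach whatever they call, so the splits say nothing of chance there; the highest others were 0, 2528 and 4.

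For the lists that camera called with a preset correlation, chance cannot be excluded in the 5 comparisons with a called list. Without particles 9 lists were reached by 32 of 60 splits (highest other 17), and with particles 8 lists by 40 (23). For particles in M1 cultures 13 lists were reached by 23 (20), in M2 cultures 6 lists by 42 (18), and for time 8 lists by 41 (17). For the interaction 0 lists were called, which all 60 splits reach (highest other 19) and which tests nothing.

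Comparisons of 3 libraries against 3 have 10 splits, too few for a share under 0.05. Each split relabelled all single-day or single-arm comparisons of its kind (phenotype, particles or time) at once. The highest other counts therefore also reflect a change in the spread shared by all 48 libraries. At days 7, 14, 21 and 28, M2 against M1 without particles gave 2920, 0, 0 and 0 genes, with highest others of 3523, 494, 0 and 29. With particles the counts were 3824, 0, 0 and 0, with highest others of 1004, 729, 0 and 13. For particles the count was 0 on each day; the highest others were 32, 407, 0 and 270 in M1 and 7829, 68, 0 and 0 in M2 cultures. Where replicate numbers were taken to pair the libraries (M1 at days 7, 14 and 28, M2 at day 28), the 4 splits that part all 3 pairs, the real one included, gave 0 genes. The 6 that keep a pair together gave at most 32, 407 and 270 in M1 and 0 in M2 cultures. These days were chosen because same-numbered libraries correlated, so higher counts when such libraries fall on one side follow from that choice. For day 28 against day 7 the counts of 1721 in M1, 1606 in M2, 1256 in M1+PE and 4321 in M2+PE cultures had highest others of 1, 0, 3 and 0.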

How the results depend on the processing

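Surrogate variables, DESeq2, library totals without TMM, the replicate block within days, the same block in fits of the 2 arms compared, the check of replicate numbers by pairs of arms, the use of the planned limma test, on computed FPKM, as an alternative to edgeR, the permutation of list means, and the fits without the 2 libraries that stand apart or without day 7 were chosen after seeing the data. In the values given here the cause was not tested, except where fewer genes or libraries enter by construction.

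M2 against M1 without particles gave 1878 genes, and 363 with surrogate variables, 418 with them and without the 2 libraries, 5088 with voom, 767 without day 7 and 898 with a 2-fold minimum. With particles the count of 3118 became 419, 301, 8052, 823 and 876 under the same settings. The time count of 7677 became 4640 and 4391 with surrogate variables, with and without the 2 libraries, and 2922 with a 2-fold minimum. Without a low-value filter 7 genes passed for particles in M1 cultures, 8 in M2 cultures and 6 for the interaction, and DESeq2 called 5 in M1 cultures and 1 for the interaction. The other settings gave 0, except 1 gene for particles in M1 cultures in the fit of the 2 arms with a replicate block. The 7 genes that varied over days became 857 without a filter, 1 without the 2 libraries, and 14 and 46 with surrogate variables. They became 15 with limma on FPKM, 16 with quantile normalization, 2742 with voom, 196 with DESeq2 and 3 in a fit of only the groups compared. The phenotype and particle comparisons of single days summed to 6744 genes, and to 2677 without the 2 libraries, 964 and 1399 with surrogate variables, 26841 with voom, 10482 with DESeq2 and 798 in fits of only the groups compared. Time in single arms summed to 8904, with voom to 24846 and in fits of only the groups compared to 4569. The 44 lists called by camera over 6 comparisons became 0 with an estimated correlation, 23 with fry and 19 by permutation in 5 comparisons.

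Leaving out 1 library of the groups compared at a time gave 1178 to 2941 genes without particles, 2135 to 4058 with particles, 0 to 0 for particles and the interaction, 7145 to 8015 for time, 1 to 335 varying genes, 4090 to 10888 over single days and 6906 to 11405 over single arms. Libraries outside the groups compared enter through the shared spread. Leaving out 1 of these gave 1753 to 2343 genes without particles, 2969 to 4357 with particles (the highest without replicate 2 of M2 at day 7) and 7534 to 7804 for time. On single days with 0 genes, M2 against M1 without particles became 1 gene at day 14 without replicate 1 or 3 of M1+PE at day 28 or replicate 2 of M2 at day 7, and 6 at day 21 without replicate 3 of M1+PE at day 28. Particles in M2 cultures at day 7 became 1 without replicate 2 of M2 at day 28. A block for the replicate number gave 1761, 2976, 0, 0, 0 and 7539 genes for the 6 mean comparisons, and 7 varying genes. Within days it gave 1648, 2767, 0, 0, 0 and 7360, and 6. In fits of the 2 arms compared, this block gave 941 and 3091 genes for M2 against M1 without and with particles, 1 and 0 for particles in M1 and M2 cultures, and 4232 over single days. Over all arms, same-numbered libraries of a day had a mean correlation of 0.03 (-0.71 to 0.77; 33 of 72 above 0.1), and 16 of 48 libraries lay closest to their own number. For M1 and M1+PE the mean was 0.38 (-0.18 to 0.77; 10 of 12 above 0.1; exact one-sided p 0.017, adjusted over 6 pairs of arms 0.102), and for the other 5 pairs of arms -0.098 to 0.021. The numbers were taken to pair the libraries in M1 and M1+PE at days 7, 14 and 28 and in M2 and M2+PE at day 28. There edgeR called 0 genes for particles with the block and without it. The p-values did shift. At day 28 in M1 cultures 228 genes had an unadjusted p under 0.05 in the main fit, and with the block more did than a uniform distribution would give.

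Of the 16 genes per comparison with the largest changes, surrogate variables left 8 past the threshold without particles, 9 with particles and 11 for time. The fit without day 7 left 12 and 13 for the phenotype comparisons. Among named genes with surrogate variables and without the 2 libraries, IL6 with particles became -1.39 log2 (adjusted p 0.0395; 0.35 before), TNF over time 1.12, KDM3A over time -0.014 and ID3 over time 0.0059. With surrogate variables on all libraries TNF over time became 1.16 and SOX17 over time 0.15. A change of sign between estimates that both missed the threshold was not counted as a reversal. The depth of 7840588 and 9381188 counts limits 2 libraries, which hold fewer counts than the other 46.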

Other observations

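The permutation test of list means was chosen only after the results were seen; the gene lists were chosen before the data were examined.

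Some pericyte markers rose between day 7 and day 28, and several contractile and TGF-beta response genes fell. Of 12 pericyte and smooth muscle markers 4 rose and 1 fell (4 and 1 adjusted over the list alone). DES, the muscle filament desmin, rose by 1.997 ± 0.33 log2 (12 libraries per day), NDUFA4L2, a mitochondrial protein induced by hypoxia, by 0.94 ± 0.18, ABCC9, a potassium channel subunit, by 0.94 ± 0.21 and STEAP4, a metalloreductase, by 1.94 ± 0.50. ANPEP, an aminopeptidase, changed by -1.33 ± 0.12. The median member changed by -0.09 log2 and the mean member by 0.20. Of 20 myofibroblast and contractile genes none rose and 5 fell (5 adjusted over the list alone), with ELN, which encodes elastin, at -3.28 ± 0.29, TAGLN, an actin-binding protein, at -1.68 ± 0.23 and TPM1, a tropomyosin with 21.4% of its exons overlapped, at -1.65 ± 0.24. Of 16 TGF-beta response genes none rose and 8 fell (1 rose and 9 fell adjusted over the list alone), with ID3, a transcriptional inhibitor, at -3.30 ± 0.55 (0.0059 with surrogate variables and without the 2 libraries that stood apart), INHBA, an activin subunit, at -3.48 ± 0.76 and TGFB1 at -0.64 ± 0.13. The permutation test gave adjusted p of 0.011 for pericyte, 0.249 for myofibroblast and 0.125 for TGF-beta genes, and 0.00515, 0.0067 and 0.00515 without the 2 libraries that stood apart. The mean log2 CPM of these lists differed by 0.33, -0.30 and -0.73 over all libraries and by 0.38, -0.47 and -1.04 without those 2. Camera gave an adjusted p = 0.952, 0.872 and 0.872 with an estimated correlation.

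Secreted angiogenic factors, sprouting genes, lymphatic markers and genes of alternative activation each had members that rose and members that fell over time. Of 23 secreted angiogenic factors 3 rose and 10 fell (4 and 10 adjusted over the list alone). HGF, the hepatocyte growth factor, rose by 2.34 ± 0.20 log2 and CXCL12, a stromal chemokine, by 3.15 ± 0.35. PDGFA and FGF2, both mitogens of mesenchymal cells, changed by -1.81 ± 0.32 and -1.21 ± 0.32. Of 23 sprouting and tip-cell genes 3 rose and 5 fell (3 and 4 adjusted over the list alone). APLN, the peptide apelin, and ANGPT2, a ligand of TEK, rose by 2.36 ± 0.30 and 2.07 ± 0.34. HEY2, a Notch target, and ESM1, a tip-cell marker, changed by -2.83 ± 0.66 and -2.04 ± 0.34. Of 6 lymphatic endothelial markers 1 rose and 2 fell (1 and 4 adjusted over the list alone), with LYVE1, a hyaluronan receptor also made by macrophages, at 3.27 ± 0.25. Of 22 genes of alternative activation 9 rose and 8 fell over time (9 and 8 adjusted over the list alone), with F13A1 at 3.45 ± 0.49 and IL10 at 3.81 ± 0.74 against CCL18 at -4.67 ± 0.53 and TGM2, a transglutaminase, at -2.70 ± 0.27. The median member changed by 0.53 and the mean member by -0.58 log2. The mean log2 CPM of the sprouting list differed by 0.09 (-0.025 without the 2 libraries that stood apart) and that of the lymphatic list by 0.06 (0.31 without them), whereas their median members changed by -0.05 and -0.88. For angiogenic factors it differed by -0.25 (-0.49 without them) and for alternative activation by -0.22 (-0.36). For these 4 lists the permutation test gave adjusted p of 0.469, 0.773, 0.811 and 0.547, and 0.018, 0.921, 0.0452 and 0.277 without the 2 libraries that stood apart. Camera gave an adjusted p = 0.952 for each with an estimated correlation. Genes named here that the rule for named genes does not include were chosen after their values were seen.

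For the remaining lists the permutation test over time did not pass, with or without those 2 libraries. Of 22 pan-macrophage markers 5 rose (3 adjusted over the list alone), of 24 genes of classical activation 6 fell (3), and of 25 phagocytosis, lysosome and foreign-body genes 5 rose and 5 fell (5 and 5). Of 19 collagens 2 rose and 7 fell (2 and 7), of 17 osteoclast genes 1 and 7 (1 and 7), of 18 osteogenic, chondrogenic and adipogenic genes 3 and 5 (3 and 5), and of 17 angiogenesis inhibitors 5 and 4 (6 and 4 adjusted over the list alone). Of 20 mesenchymal markers 5 rose and 6 fell (5 and 7), of 20 synovial sublining genes 7 and 7 (8 and 7), of 19 heat-shock and immediate-early genes 6 and 2 (6 and 2), and of 24 ribosomal protein genes 1 and 5 (0 and 5). Median and mean members differed in sign for angiogenesis inhibitors (0.21 and -0.25 log2) and for mesenchymal markers (-0.086 and 0.0038 log2); for collagens and sublining genes both were below 0 while the mean log2 CPM differed by 0.08 and 0.09.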
